A study of Homo sapiens with 3 samples.

How the data were processed

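TU-177 cells were grown in MEM with 10% fetal bovine serum, and CD133+CD44+ and CD133-CD44- cells were isolated with magnetic beads, per the labels' protocols. RNA of 3 samples per group was pooled in equal amounts, depleted of rRNA and made into a strand-marked (dUTP) library, so each of the 3 groups is 1 library with no replicate. The submitters' processing notes name Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, Cuffdiff 2.1.1 and the build hg19, with no role or order for any of them.

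The deposited mRNA and lncRNA values are FPKM per transcript as the authors computed them; any scaling between libraries and any filter are not given in the sources used here. Because FPKM divides by transcript length, a few reads on a very short transcript give a large value, and depth and counting error cannot be recovered. The mRNA files hold 81494 transcripts of 20139 genes and the lncRNA files 5268 transcripts of 3689 genes; 29 mRNA genes have a symbol stored as a date and were kept by their gene identifier. Linear genes of circRNA junctions were looked up by symbol, and a symbol that was not found added 0 to a sum over several genes. Among junctions with at least 20 reads, 2 of a gene with such a date symbol, SEPT7, and hg19_circ_0003752 of SLC35E2A had no FPKM above 0. They were left out of the comparisons of junction reads with mRNA. Values listed at 0 can be failed estimates, so no fold is given against them. The deposited circRNA files are named TPM, but each column sums to 1000000 and every value is a whole multiple of the same step (within 1.6e-07 of a whole number), so the values are RPM, junction reads scaled to a total of 1000000 per library, without a length correction. No value of 1 step occurs, so a listed 0 is taken here as fewer than 2 reads, an assumption from the values alone. Junction reads came to 14627 (CD133+CD44+), 13357 (CD133-CD44-) and 14784 (unsorted), a depth at which a junction of 10 reads carries a wide interval.

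FPKM of transcripts were summed per gene. Log2 ratios used a pseudocount of 1 FPKM for mRNA and 0.1 FPKM for lncRNA, which understates changes of low genes. Genes needed 1 FPKM (mRNA) or 0.1 FPKM (lncRNA) in at least 1 of the libraries compared, and counts are of genes at least 2-fold apart. No test was run and no p-value computed, since groups have 1 library. The comparisons, thresholds, 35 mRNA gene lists and 1 lncRNA list were fixed before the data were examined. Alternatives named below as added, the search for linear matches and most tests of the closing paragraphs were chosen after results had been seen. For a list with at least 5 members of 1 FPKM in at least 1 library, the median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean expression, as a description of these libraries; it was called outside the range when it lay beyond the central 95%. That held for 32 lists; sort markers, fibroblast and endothelial lists had fewer members and are given gene by gene. Symbols of CD24, UHRF1, SC5DL and PECAM1 and 8 lncRNA symbols were not matched and are not analysed here; CXCL8 is analysed under its listed symbol, IL8.

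CircRNA ratios compare RPM values, and junctions needed 10 reads over the libraries compared. Intervals are exact conditional binomial (Clopper-Pearson) intervals at 95%, and shares of reads have Wilson intervals. A fold against 0 reads was computed against a floor of 3 reads in that library. Such a fold takes the reads of the other library as exact, so it is no lower bound. Reads carry no molecular identifiers, so intervals cover counting error only. The 27 nt on each side of a junction were matched to exon ends of GENCODE 29 transcripts on GRCh38, a different build from hg19; coordinates come only from that match, which gave a gene for 4367 of 5933 junctions above 0. The whole 54 nt were also searched in linear transcripts, with 1 side exact and at most 2 mismatches in the other.

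A rule fixed beforehand set which genes can be named. It takes the 12 highest and 12 lowest mRNA log2 ratios between the sorted libraries, and 5 and 5 in the other comparisons, among genes with at least 5 FPKM. It adds CD44, PROM1, the highest and lowest list members and those past 2-fold, the fixed lncRNA, and the 5 and 5 most extreme lncRNA (at least 1 FPKM) and circRNA. The 3 most abundant circRNA per library complete it, and junctions ranked against 0 reads used the floor. The mRNA genes at the extremes are all named, but only part of the list members, fixed lncRNA and other lncRNA and circRNA extremes that the rule allows are, and that part was picked after the values were seen. MAN1A2, FAT1 and HIPK3 junctions, LCN2, SOX2, S100A9, PTPRC and some further list members were chosen after their values were seen.

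Alternatives were other pseudocounts (0.1 FPKM for mRNA; 0.01 and 1 FPKM for lncRNA), other minimums (5 FPKM, 1 FPKM, none; 5 and 20 reads), scaling to the same total FPKM or by median ratios, the most abundant transcript in place of the sum, and intervals for circRNA. Added after seeing the data were sums over transcripts of at least 500 nt, sums over transcripts above 0 in all 3 libraries, scaling without mitochondrial genes, list medians after scaling to the same total, and circRNA without linear matches. The code was tested on simulated libraries: all 200 genes changed by 1.5 on the log2 scale between the sorted libraries were counted as 2-fold, together with 66 unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.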

Results

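The series compared 3 populations of TU-177, an established cell line from a laryngeal squamous carcinoma: cells sorted with magnetic beads for the surface proteins CD133 and CD44 (CD133+CD44+), cells sorted for the absence of both (CD133-CD44-), and unsorted cells. Per the labels, the sorted cells were cultured before RNA extraction, equal amounts of RNA from 3 samples of a group were mixed, and 1 rRNA-depleted, strand-marked library was sequenced per group. Each library gave mRNA, lncRNA and circRNA values. The mRNA files listed 20139 genes, of which 12572 reached 1 FPKM in at least 1 library; the lncRNA files listed 3689 genes, and 5933 circRNA junctions were above 0. Read depth behind the FPKM values is unknown. The circRNA values came from 14627 junction reads in the CD133+CD44+ library, 13357 in the CD133-CD44- library and 14784 in the unsorted library. With 1 library per group, no difference below has a replicate check, and no p-value is given.

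The genes of the sorted proteins were read first, as a check of the labels. CD44, which encodes the hyaluronan receptor used for the sort, stood at 144 FPKM in the CD133+CD44+ library, 133 FPKM in the CD133-CD44- library and 84.5 FPKM in the unsorted library, so the library labelled CD44-negative did not have less CD44 mRNA than the unsorted cells. PROM1, which encodes CD133, was listed at 0.309, 0.0195 and 0 FPKM in the same order, below the 1 FPKM minimum everywhere. The log2 ratio of CD133+CD44+ to CD133-CD44- was 0.11 for CD44. Surface protein was not measured in these files, and genes used to choose the cells are no finding.

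The first comparison asked which genes separate CD133+CD44+ cells, called cancer stem cells in the labels, from CD133-CD44- cells. Mitochondrially encoded mRNAs were higher in the CD133+CD44+ library in 13 of 13 members (median log2 ratio 0.60, percentile 100 of 10000 random lists matched on mean expression). MT-ND4L and MT-CO1, subunits of respiratory complexes I and IV, stood at 23368.5 and 13502.5 FPKM against 13095 and 8562 FPKM, while 20 nuclear-encoded respiratory chain subunits had a median of 0.02. Interferon-induced genes were lower in 21 of 22 members (median -0.35, percentile 0), among them the antiviral GTPases MX1 (16.9 against 29.8 FPKM) and MX2 (3.15 against 5.71 FPKM). Immediate early genes, which cells switch on within minutes of a stimulus, were lower in 20 of 20 members (median -0.19, percentile 0), with EGR3 and FOSB lowest (log2 ratios -0.71 and -0.67).

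Cell cycle lists moved apart by small amounts. G2/M genes had a higher median in the CD133+CD44+ library (0.13 over 23 members, percentile 100), led by HMMR and TTK at 0.35 and 0.28. G1/S genes had a lower median (-0.14, with 19 of 21 members below 0), with the replication factors GINS2 and MCM5 at -0.34 and -0.26, and replication-dependent histones were lower in 19 of 20 members (median -0.20, percentile 0). Unfolded protein and integrated stress response genes were higher in 15 of 16 members (median 0.25, percentile 100), with the stress transcription factor DDIT3 at 40.4 against 27.7 FPKM and asparagine synthetase, ASNS, at 141 against 101 FPKM. NF-kB and inflammatory cytokine genes had a lower median (-0.26 over 14 members, percentile 0), with the chemokine genes CXCL3 and CXCL2 at -0.61 and -0.59, although ICAM1 and IL6 went the other way (0.42 and 0.26). Part of these sizes depends on scaling. Rescaling to the same total without mitochondrial genes shifted the median of all genes by 0.02. Rescaling to the same total FPKM with them shifted it by -0.09. Medians were then 0.03 for G2/M genes, -0.23 for G1/S genes, -0.30 for histones, 0.15 for stress response genes and -0.29 for immediate early genes. All 5 still lay outside the random range. Scaling moves the random lists by nearly the same amount, so staying outside was nearly fixed beforehand and is no separate check.

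Lists tied to stem cell identity did not separate the sorted libraries. Pluripotency and stem cell regulators had a median of -0.06 over 8 of 15 members, from BMI1 at 0.05 to KLF4 at -0.26. SOX2, a pluripotency factor, stood at 7.29 against 8.41 FPKM. POU5F1, NANOG, LIN28A, LIN28B and TERT were among those under 1 FPKM in every library, so the median does not cover them. Surface and enzyme markers used for head and neck cancer stem cells had a median of -0.01 over 12 members, with the efflux transporter ABCG2 at 1.79 against 0.807 FPKM and the aldehyde dehydrogenase ALDH3A1 at 73.4 against 87.0 FPKM. Medians of ABC transporters (-0.03), Wnt targets (-0.07), hedgehog genes (-0.09), epithelial adhesion genes (0.01), mesenchymal genes (-0.03) and YAP targets (0.03) also lay within the range of random lists. Suprabasal squamous genes (0.16 over 12 members, with S100A9 at 16.5 against 8.37 FPKM), hypoxia genes (0.11, with PFKFB3 lowest at -0.71), basal squamous genes (0.07, with KRT16 highest at 0.73) and Notch genes (-0.13) lay just outside it. Those 4 medians fell back inside the range under at least 1 alternative. Rescaling to the same total FPKM gave 0.08, 0.03, -0.03 and -0.21, so the basal squamous median turned negative. In all, 12 of 32 lists stood outside the range in this comparison, where lists of randomly drawn genes would put 1.6. Random draws ignore that members of a list can vary together, and some lists share members. With 1 library per group, the 1.6 is therefore no chance value for a difference between the cells.

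Among 12339 genes with at least 1 FPKM in either sorted library, 36 were at least 2-fold higher and 19 at least 2-fold lower in the CD133+CD44+ library (0.446%). Of these, SPRR2D, a cornified envelope gene at 1.46 against a listed 0 FPKM, was the member of a fixed list. IL6ST, the shared receptor subunit of IL-6 family cytokines, stood at 194 against 8.08 FPKM (6.91 FPKM unsorted), but 185 FPKM of that came from a transcript of 168 nt that was listed at 0 in the other 2 libraries. MLLT10 (56.6 against 12.2 FPKM), CDKL1 (14.0 against 4.59 FPKM), PNRC2 (65.2 against 199.5 FPKM) and WDFY3 (10.9 against 23.6 FPKM) likewise differed through 1 transcript of 171 to 240 nt listed at 0 in 1 sorted library. LUZP6, annotated inside the MTPN locus, was listed at 70.5 FPKM in the CD133-CD44- library and at 0 in both others. All of that value came from 1 transcript of 177 nt. TMEFF1 (6.06 against 0.190 FPKM) and the readthrough gene MSANTD3-TMEFF1, which shares its exons, went opposite ways (0.000911 against 5.66 FPKM). Most other genes at the extremes carried clone-based or provisional names, such as AP001350.1 (135 against a listed 0 FPKM), AC018630.1 (33.0 against 0), AC132192.1 (8.84 against 1.60), AL109927.1 (405 against 159), RP4-583P15.14 (5.74 against 0) and C20ORF135 (7.70 against 2.62), or on the lower side RP11-977G19.10 (1.11 against 12.4), AC092291.2 (0 against 6.84), AL133262.1 (0 against 6.65), RP11-286N22.8 (1.42 against 6.29), AC092964.2 (2.59 against 8.88) and KIAA1658 (2.03 against 5.39). RPL36A-HNRNPH2 (8.74 against 3.16 FPKM), CKB, the brain-type creatine kinase (7.01 against 3.19 FPKM), FAM160A1 (4.08 against 10.4 FPKM) and KLHL13 (3.62 against 8.11 FPKM) completed the 24 genes at the extremes above 5 FPKM. Libraries simulated with no change gave 67 such genes, but the simulation took its spread from these same libraries. The count was 23 when only transcripts above 0 in all 3 libraries were summed and 144 with a pseudocount of 0.1. The excess on the higher side was gone in the former (12 higher, 11 lower), with a minimum of 5 FPKM (11 and 11) and with the most abundant transcript (61 and 61). Across genes, log2 values of the sorted libraries correlated with Pearson's r = 0.992, where genes are not independent replicates.

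**Figure D1:**
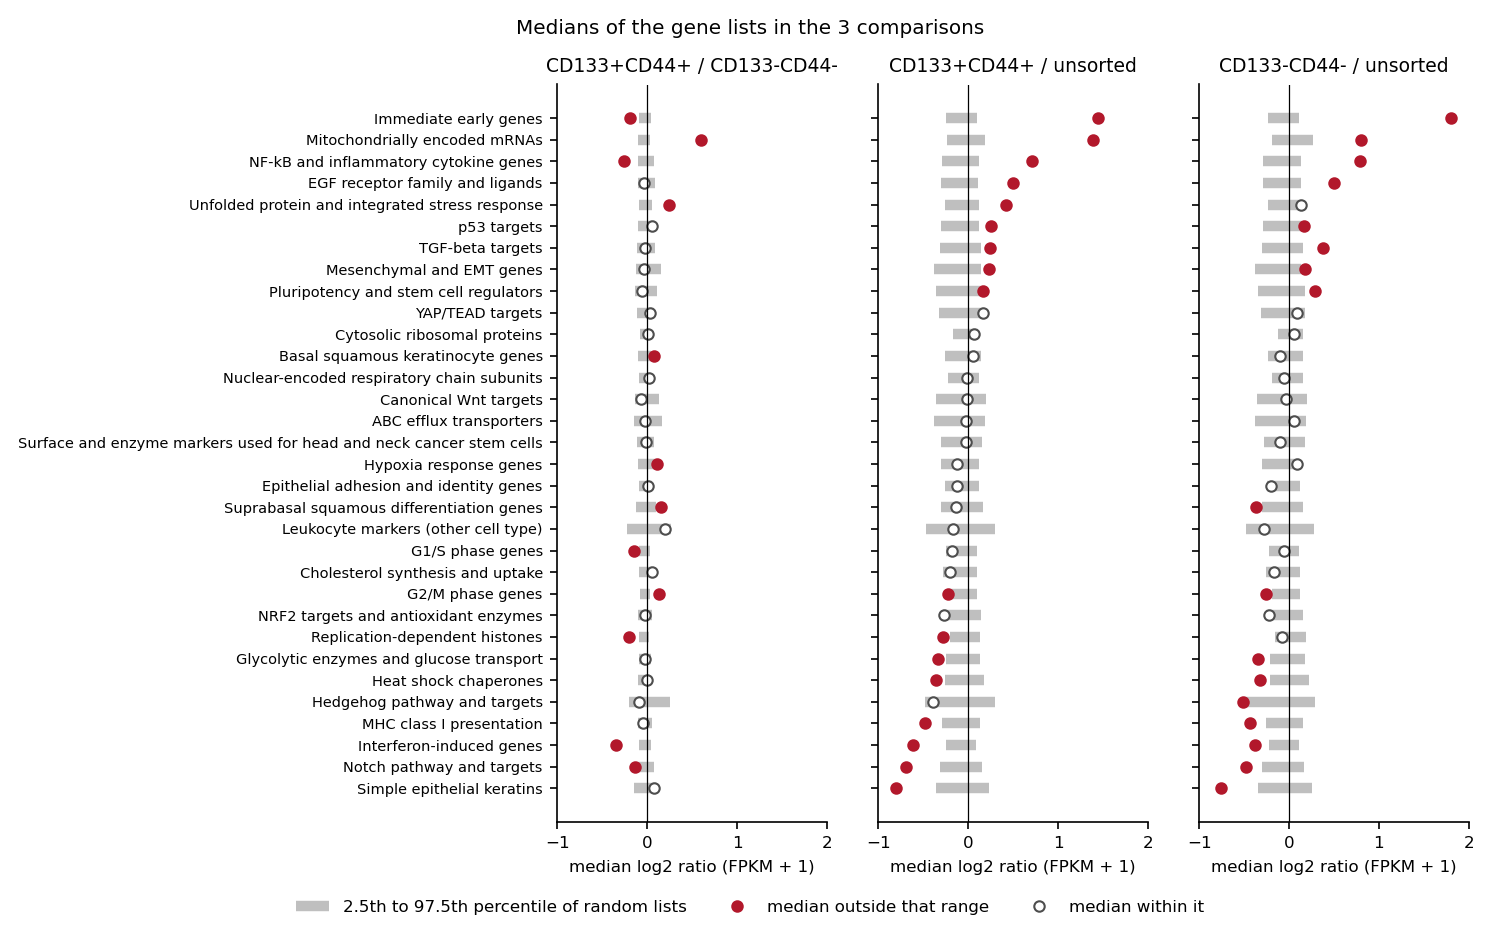
Medians of log2((FPKM + 1)/(FPKM + 1)) over the members of 32 gene lists (horizontal axis, log2) in the 3 comparisons, 1 panel each; grey bars span the central 95% of 10000 random lists matched on mean expression, and filled points lie outside them. Immediate early genes stand at 1.45 and 1.81 in the sorted libraries against the unsorted library and at -0.19 between the sorted libraries.

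The next comparisons set each sorted library against the unsorted cells. Immediate early genes had the highest medians of all lists, 1.45 for CD133+CD44+ (14 of 20 members at least 2-fold higher) and 1.81 for CD133-CD44- (15 of 20), both at percentile 100. The AP-1 gene FOSB stood at 48.0 and 77.1 FPKM in the sorted libraries against 2.84 FPKM unsorted, FOS at 238 and 316 against 29.4, the stress factor ATF3 at 30.7 and 34.0 against 2.91, the phosphatase gene DUSP1 at 93.9 and 104.5 against 10.8, and the matricellular gene CTGF at 54.4 and 67.5 against 6.58. NR4A1, KLF6, CYR61, EGR1 and JUN had log2 ratios of 2.08, 1.96, 2.03, 1.71 and 1.60 in CD133+CD44+ and 2.57, 2.23, 2.15, 2.01 and 1.69 in CD133-CD44-. Members that did not follow were JUND (37.3, 39.1 and 37.3 FPKM) and BTG2 (2.07, 2.16 and 2.52 FPKM). NF-kB and inflammatory cytokine genes had medians of 0.71 and 0.79, with IL8 at 65.4 and 85.7 against 23.9 FPKM, CCL20 at 16.0 and 20.8 against 3.72, IL6 at 17.8 and 14.8 against 4.35 and LIF at 21.6 and 23.9 against 8.52; NFKBIA had log2 ratios of -0.52 and -0.15. EGF receptor family genes and ligands had medians of 0.49 and 0.50, with the ligand genes AREG (78.4 and 83.1 against 33.5 FPKM) and EREG (55.5 and 73.8 against 22.9 FPKM) and the ERK-induced DUSP6 (20.2 and 21.2 against 5.93 FPKM) at least 2-fold higher, while ERBB2 (36.5 and 39.9 against 59.5 FPKM) and ERBB3 had log2 ratios below 0.

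Mitochondrially encoded mRNAs were also higher in both sorted libraries, with medians of 1.39 and 0.80 and all 13 members above 0 in each. Their genes took 22.9% of all mRNA FPKM in the CD133+CD44+ library, 16.1% in the CD133-CD44- library and 9.03% in the unsorted library, so this share moved with every group difference given here. MT-ND4L stood at 23368.5, 13095 and 4489 FPKM, further apart than the list medians in both comparisons. The endoplasmic reticulum chaperone gene HSPA5 was at 439.5 and 363 against 106 FPKM, and HERPUD1, of the same stress response, at 70.9 and 55.8 against 22.3 FPKM; the median of their list was 0.42 for CD133+CD44+ (percentile 100) and 0.14 for CD133-CD44-, which lay within the random range.

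Interferon-induced genes were lower in both sorted libraries (medians -0.62 and -0.38, percentile 0 in each), and 7 of 22 were at least 2-fold lower in CD133+CD44+: MX1 (16.9 against 58.2 FPKM), OAS2 (10.6 against 31.0), OAS1 (20.4 against 52.6), IFI44L (19.7 against 49.6), XAF1 (5.45 against 12.7), OAS3 (53.9 against 114) and MX2 (3.15 against 7.53). IFIT2 went the other way, at 29.4 against 22.7 FPKM. In CD133-CD44-, 0 of 22 were at least 2-fold lower, and IFIT2, IFIT3 and IFI44 were above 0 (log2 ratios 0.43, 0.20 and 0.13). Simple epithelial keratins and mucins had the lowest medians (-0.80 and -0.76 over 7 members), with KRT19 at 720 and 700.4 against 1556 FPKM and MUC16 at 1.14 and 0.890 against 3.35 FPKM. Notch genes had medians of -0.70 and -0.48, with the receptor gene NOTCH1 at 22.6 and 22.0 against 51.7 FPKM and HES1, a Notch target, above 0 in both (0.36 and 0.55). Genes of MHC class I presentation (-0.48 and -0.43), heat shock chaperones (-0.36 and -0.32), glycolytic enzymes (-0.33 and -0.35) and G2/M genes (-0.22 and -0.26) were lower as well, as were histones in CD133+CD44+ (-0.27) and suprabasal squamous genes in CD133-CD44- (-0.37). HSPA1A and HSPA1B were at 143 and 166 FPKM in CD133+CD44+ and 134 and 156 in CD133-CD44- against 327 and 398 unsorted, but they are near-identical copies whose reads cannot be told apart. The G2/M median of CD133+CD44+ lay at percentile 2.38 and fell back inside the random range under 4 alternatives. Rescaling to the same total FPKM moved the medians of CD133+CD44+ to 0.30 for EGF receptor genes, 0.21 for stress response genes, -0.55 for glycolytic enzymes, -0.58 for heat shock chaperones, -0.50 for histones and -0.44 for G2/M genes, on the same sides of 0.

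In counts, 161 genes were at least 2-fold higher and 95 at least 2-fold lower in CD133+CD44+ than in unsorted cells (12489 tested), and 135 and 79 in CD133-CD44- (12474 tested). Named by rule were the highest values, AP001350.1, IL6ST, AC016559.1 (19.5 and 13.1 FPKM against a listed 0), AL136218.1 (16.8 and 17.4 against 0), AC007382.1 (14.3 and 9.93 against 0), LUZP6 and FOSB, and the lowest, RP11-977G19.10, AC092291.2, RNF103-CHMP3 (0.759 and 0.6075 against 5.17), the apolipoprotein gene APOC1 (2.81 and 4.38 against 11.7), MX1, AC018630.1, SBP1 (2.51 and 1.18 against 9.27), AC132192.1 and TXNIP, a glucose-responsive thioredoxin inhibitor (20.6 and 14.2 against 45.3). The same 102 genes were higher and 36 lower in both sorted libraries. Independent lists of these sizes would share 1.75 and 0.606 genes. Simulated libraries with no change shared 10 and 13 through the common unsorted library, so part of the excess may come from that library. The simulated spread was taken from the sorted libraries, so a noisier unsorted library is not covered. Rescaling to the same total FPKM shifted the median of all genes by -0.20 and -0.11 on the log2 scale. It turned the splits to 111 higher and 230 lower and to 102 higher and 167 lower. Median ratio scaling gave 196 and 59, and 156 and 58. Rescaling to the same total without mitochondrial genes shifted the median by only 0.0145 and -0.00512. The larger shifts thus came from the mitochondrial share of FPKM.

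Of 344 genes with a range of at least 2-fold over the 3 libraries, the unsorted library was the furthest from the others in 264 (76.7%), CD133+CD44+ in 48 and CD133-CD44- in 32. The unsorted library held the middle value in 37 genes, CD133+CD44+ in 134 and CD133-CD44- in 173, where exchangeable error gives the same share to each library. In simulated libraries with no change, the unsorted library was furthest in 30.6% of varying genes. That simulation gave all 3 libraries the same spread, taken from the sorted libraries, so near-equal shares were built in. It cannot show what a noisier unsorted library would give.

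**Figure D2:**
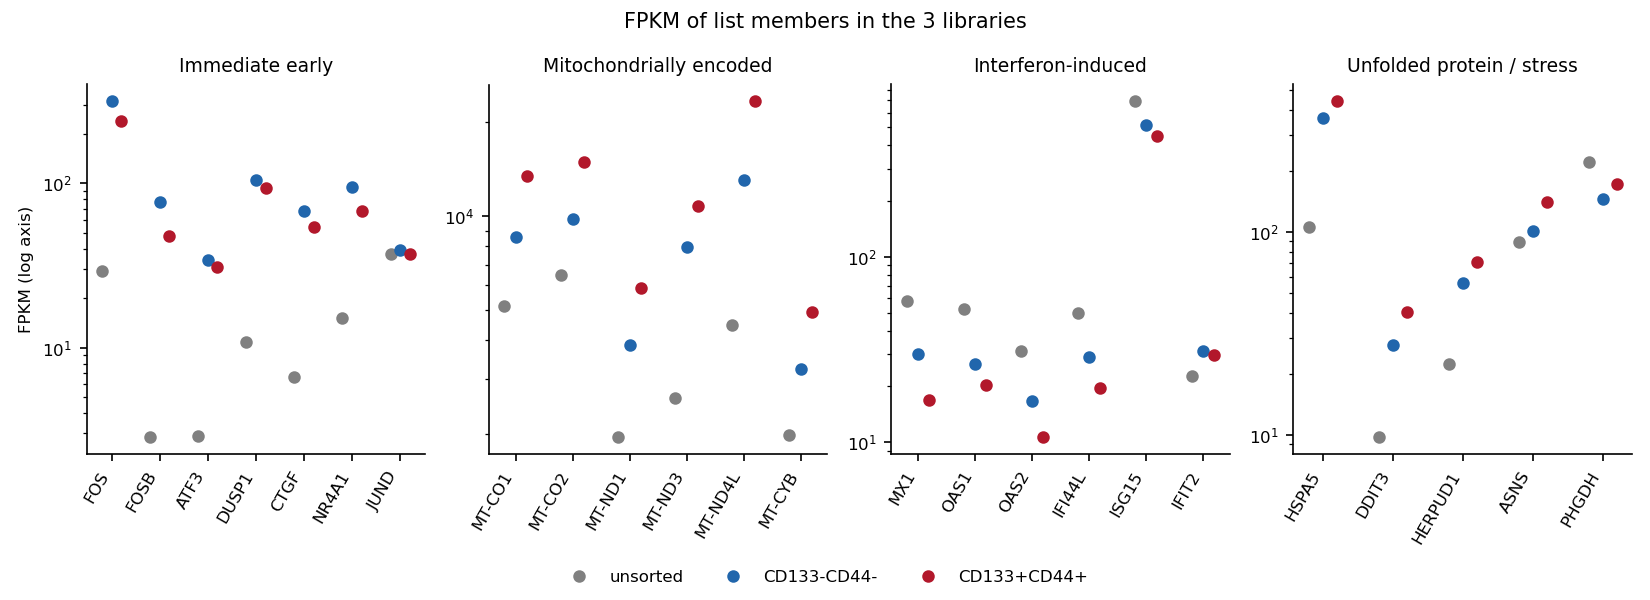
FPKM (log axis) of members of 4 gene lists in the unsorted (grey), CD133-CD44- (blue) and CD133+CD44+ (red) libraries, 1 point per library. FOS lies at 29.4, 316 and 238 FPKM and MX1 at 58.2, 29.8 and 16.9 FPKM in that order.

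Lists of other cell types were read for admixed cells. The leukocyte gene PTPRC was at 0.0102, 0.0113 and 0.0768 FPKM in CD133+CD44+, CD133-CD44- and unsorted libraries, and the 5 leukocyte list members above 1 FPKM had medians within the random range in the 3 comparisons, with CD68 highest at 21.8, 17.4 and 12.1 FPKM. CD68 and LCP1 (3.86, 2.72 and 1.87 FPKM) were higher in both sorted libraries, and CD14 (1.60, 1.97 and 2.59 FPKM), CD74 and HLA-DRA lower. Of the fibroblast list, TAGLN (4.67, 3.22 and 6.44 FPKM), COL1A1 (7.59, 8.10 and 9.29) and ACTA2 (1.16, 1.29 and 1.47) exceeded 1 FPKM. Of the endothelial list, EGFL7 (21.1, 24.7 and 28.7 FPKM) and CDH5 (5.43, 6.51 and 8.56) did. Those 2 lists had too few members for a median.

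For lncRNA, the question was the same. None of 25 fixed lncRNA with at least 1 FPKM differed 2-fold between the sorted libraries (median log2 ratio -0.01). Of these 25, UCA1, an lncRNA linked to carcinoma growth, came closest at 16.1 against 9.34 FPKM (log2 ratio 0.78), with 6.07 FPKM unsorted. Under 1 FPKM but above the 0.1 FPKM minimum, the fixed lncRNA SOX2-OT was past 2-fold. It stood at 0.573 against 0.155 FPKM (log2 ratio 1.40), with 0.41 FPKM unsorted. Against unsorted cells, 4 of the 25 were at least 2-fold higher and 2 lower in CD133+CD44+ (median 0.23), and 2 were higher in CD133-CD44- (median 0.36). Of the host genes of small nucleolar RNAs in the list, ZFAS1 stood at 113 and 111 against 48.4 FPKM, SNHG8 at 153 and 149 against 75.1, GAS5 at 187 and 187 against 96.4, and SNHG5 at 567.5 and 505 against 331, while log2 ratios for CD133+CD44+ and CD133-CD44- were -0.15 and 0.06 for SNHG15, 0.20 and 0.32 for SNHG1 and 0.16 and 0.54 for SNHG12. MIR22HG stood at 14.6 and 14.2 against 6.51 FPKM, and the nuclear lncRNAs MALAT1 and NEAT1 at 4928 and 4653 against 2764 FPKM and at 412 and 414 against 286 FPKM. The imprinted lncRNA H19 stood at 736 and 986.5 against 1635 FPKM, and TINCR, which acts in epidermal differentiation, at 0.707 and 0.892 against 1.78 FPKM.

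Over all lncRNA, 431 were at least 2-fold higher and 382 at least 2-fold lower in CD133+CD44+ than in CD133-CD44- cells, of 3221 with at least 0.1 FPKM in either library (25.2%, with a pseudocount of 0.1 FPKM). With a pseudocount of 1 FPKM, the count was 152. The extremes above 1 FPKM were RP3-508I15.20 (98.8 against a listed 0 FPKM), RN7SL81P (16.0 against 0), RN7SL141P (7.78 against 0), RN7SL57P (5.28 against 0) and RP4-794H19.1 (10.7 against 0.102), and AP001271.3 (0 against 18.2), RP11-21L19.1 (0 against 11.3), RN7SL204P (0 against 3.60), RN7SL12P (0 against 2.98) and RP11-96C21.1 (0 against 2.89). The RN7SL names belong to a family of near-identical copies of 7SL RNA, so their values are uncertain. Against unsorted cells, 469 lncRNA were at least 2-fold higher and 495 lower in CD133+CD44+, and 470 and 536 in CD133-CD44-. The lowest in both was CTC-246B18.10 (listed at 0 in both sorted libraries against 221 FPKM unsorted). The highest was RP3-508I15.20 in CD133+CD44+ (98.8 against a listed 0 FPKM) and RP11-98F14.11 in CD133-CD44- (35.8 against a listed 0 FPKM).

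CircRNA, closed loops joined by back-splicing, were compared as junction reads, with intervals for counting error only. Of 5933 junctions above 0, 694 were above 0 in all 3 libraries and 4387 in only 1. Among 474 with at least 10 reads over the sorted libraries, 71 were at least 2-fold higher and 60 at least 2-fold lower in CD133+CD44+. Of these 131, 42 had a 95% interval that excluded an equal rate. The intervals are not adjusted for the 474 junctions, so some would exclude it by counting error alone. Junctions named below as extremes were picked from that set by their ratios. The most abundant junction whose ends matched exon ends of 1 gene was hg19_circ_0001834, exons 2 to 11 of the kinase gene VRK1 (chromosome 14, 96833467 to 96860735, GRCh38), with 261 reads in CD133+CD44+, 219 in CD133-CD44- and 249 in unsorted cells (ratio of the sorted libraries 1.09, 95% interval 0.906 to 1.31). Other abundant junctions had ratios with intervals that included an equal rate: hg19_circ_0003608, exons 2 to 5 of MAN1A2 (91, 81 and 114 reads), hg19_circ_0006198, exon 2 of FAT1 (82, 67 and 71 reads), and hg19_circ_0000558, exon 2 of HIPK3 (64, 75 and 59 reads; ratio 0.779, 95% interval 0.549 to 1.10).

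At the extremes between the sorted libraries was hg19_circ_0003110, exons 3 to 4 of the ubiquitin ligase gene RNF138 (chromosome 18, 32111754 to 32113860, GRCh38). It had 24 reads in CD133+CD44+ and 26 in unsorted cells against 0 in CD133-CD44-. With the 0 set to a floor of 3 reads and the 24 taken as exact, it was 7.31-fold higher in CD133+CD44+. The ZMYM4 junction hg19_circ_0004188, exons 3 to 5, had 18, 0 and 8 reads (5.48-fold against that floor). The junction hg19_circ_0007034, exons 2 to 3 of FAM120B, had 11, 2 and 0 (ratio 5.02, 95% interval 1.10 to 46.6). On the lower side, hg19_circ_0007201, exons 5 to 7 of PHIP, had 3, 18 and 8 reads (ratio 0.152, 95% interval 0.0287 to 0.521), and hg19_circ_0006797, exons 20 to 21 of FCHO2, had 2, 12 and 0 (ratio 0.152, 95% interval 0.0165 to 0.684). The junctions hg19_circ_0008488 (10, 2 and 3 reads, ratio 4.57, 95% interval 0.973 to 42.9) and hg19_circ_0007265 (2, 10 and 0 reads, ratio 0.183, 95% interval 0.0195 to 0.857) matched no annotated exon ends. Of the 10 junctions at the extremes, 3 had sequences that also occur in a linear transcript. With folds against the same floor, these were hg19_circ_0001236 (231, 0 and 0 reads, 70.3-fold higher), hg19_circ_0002073 in CD276 (0, 31 and 0, 11.3-fold lower) and hg19_circ_0003753 (0, 17 and 11, 6.21-fold lower).

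Such junctions, 172 of 5933 above 0, held 22.2%, 22.7% and 28.2% of junction reads in CD133+CD44+, CD133-CD44- and unsorted libraries, and included the most abundant of all, hg19_circ_0001200 (691, 713 and 870 reads; the tubulin gene TUBA1B and its pseudogene TUBAP2), and hg19_circ_0002394 (162, 130 and 229 reads; metallothionein genes). Against unsorted cells, 129 of 483 junctions differed 2-fold in CD133+CD44+ and 145 of 460 in CD133-CD44-. Of these, 54 and 59 had intervals that excluded an equal rate, again without adjustment for the number of junctions. Highest in CD133+CD44+ after hg19_circ_0001236 was hg19_circ_0008517, which matched no annotated exon ends, with 28 and 10 reads against 3 (ratio 9.43, 95% interval 2.91 to 48.5). The FAM13B junction hg19_circ_0006449, exons 8 to 10, had 20 and 12 reads against 4 (ratio 5.05, 95% interval 1.69 to 20.3, for CD133+CD44+). Lowest in both was hg19_circ_0003737, whose sequence occurs in linear transcripts of CDK11A and CDK11B. It had 0 and 0 reads against 31 (10.2-fold and 9.34-fold lower against the floor of 3 reads). Next to it, hg19_circ_0002546, exons 2 to 4 of BANP, had 2 and 2 reads against 19 (ratio 0.106, 95% interval 0.0120 to 0.441, for CD133+CD44+), and hg19_circ_0002808, exons 3 to 6 of KANSL1, had 13 and 3 against 21 (ratio 0.158, 95% interval 0.0302 to 0.530, for CD133-CD44-).

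**Figure D3:**
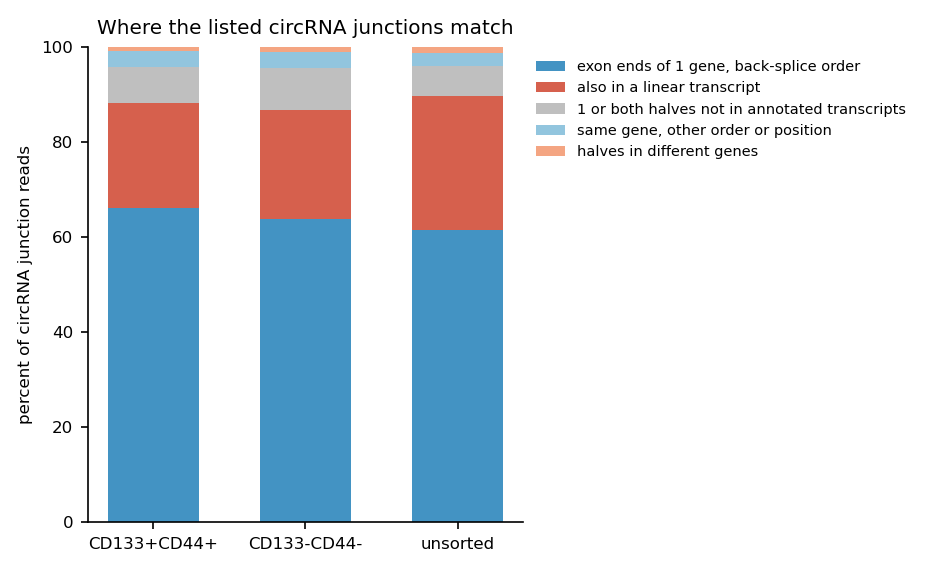
Percent of circRNA junction reads (vertical axis) in each library by where the 54 nt of a junction match annotated transcripts. Junctions found in a linear transcript hold 22.2% of reads in CD133+CD44+, 22.7% in CD133-CD44- and 28.2% in unsorted cells.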

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

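The search for linear matches and the comparisons of ratios between libraries were chosen after the most abundant junctions had been seen. The circRNA files hold a sequence for each junction, which the planned counts of reads do not use. It showed that 22.2% of junction reads in CD133+CD44+ (95% Wilson interval 21.5 to 22.9%), 22.7% in CD133-CD44- (22.0 to 23.4%) and 28.2% in unsorted cells (27.5 to 28.9%) sit at junctions whose 54 nt also occur in an annotated linear transcript. Whether these shares are unusual was not tested. Of the 172 junctions, 116 match a linear transcript without a mismatch.

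Reads of ordinary spliced mRNA from paralogous or duplicated exons are a candidate explanation. Across 87 such junctions with at least 10 reads, reads rose with the FPKM of the genes that hold the linear sequence (Spearman's rho 0.39, bootstrap interval 0.18 to 0.57), against 0.17 for 553 other junctions and their host genes; junctions are not independent replicates, and the lower bound clears that value by a small margin. For example, the tubulin junction hg19_circ_0001200 had 691, 713 and 870 reads where TUBA1B stood at 770, 791 and 975 FPKM in CD133+CD44+, CD133-CD44- and unsorted libraries. Back-splicing in these genes stays open: ratios between libraries lay within 2-fold of the mRNA ratios in 65.3% of 72 junctions with at least 20 reads and 92.3% of the 26 with at least 100, but also in 51.7% of 201 and 76.9% of 13 other junctions set against their host genes. Exceptions to the mRNA account include hg19_circ_0001236 (KRT6B and KRT6C; 231, 0 and 0 reads with linear genes at 1.14, 1.34 and 1.52 FPKM), hg19_circ_0002073 (CD276; 0, 31 and 0 reads at 16.4, 18.3 and 24.2 FPKM) and hg19_circ_0003737 (CDK11A and CDK11B; 0, 0 and 31 reads at 77.0, 71.9 and 77.4 FPKM).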

How the results depend on the processing

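Sums over transcripts of at least 500 nt or above 0 in all 3 libraries, list medians scaled to the same total FPKM and circRNA without linear matches were settings chosen after results were seen. Counts of mRNA genes past 2-fold moved by over 1.5 times under some settings, and the cause was not tested beyond what each setting removes. Between the sorted libraries the 55 genes became 144 with a pseudocount of 0.1 FPKM, 22 with a minimum of 5 FPKM and 122 with the most abundant transcript. They became 36 with transcripts of at least 500 nt and 23 with transcripts above 0 in all 3 libraries. Against unsorted cells, a pseudocount of 0.1 gave 504 in place of 256 for CD133+CD44+ and 504 in place of 214 for CD133-CD44-, and the most abundant transcript gave 379 for the latter. The 813 lncRNA became 152 with a pseudocount of 1 FPKM and 320 with a minimum of 1 FPKM. The 131 circRNA became 491 with a minimum of 5 reads, 27 with 20 reads and 42 when the interval had to exclude an equal rate; leaving out junctions with a linear match gave 113. The unsorted library was the furthest in 71.0 to 85.9% of varying genes as reported, with a pseudocount of 0.1, a minimum of 5 FPKM and median ratio scaling. The CD44 log2 ratio between the sorted libraries was 0.11 to 0.12 as reported, with the most abundant transcript and with median ratio scaling. Neither was run with scaling to the same total FPKM, which shifted the median of all genes by -0.09 between the sorted libraries. Of 46 list medians outside the random range, 45 kept their side with a pseudocount of 0.1 and with median ratio scaling, and 43 with scaling to the same total FPKM. Both scalings move the random lists along with a list, so the counts under scaling were nearly fixed beforehand. Of 45 that could be computed, 40 kept it with a minimum of 5 FPKM, 40 with the most abundant transcript and 39 with transcripts above 0 in all 3 libraries. Scaling to the same total FPKM turned 2, basal squamous genes between the sorted libraries to -0.0282 and stem cell regulators of CD133+CD44+ against unsorted to -0.0482. No paired analysis was possible because each group has 1 library. Unknown FPKM depth limits the mRNA and lncRNA values, and few reads per junction limit the circRNA ratios.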

Other observations

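All tests below except that of transcript length in immediate early genes were chosen after results bearing on them had been seen, and the test of overlapping genes was at first set aside after its result was known, then restored unchanged. Several gene groups not described above also stood apart from unsorted cells. p53 targets had medians of 0.25 in CD133+CD44+ and 0.17 in CD133-CD44- (0.06 in each after scaling to the same total FPKM), with the cytokine gene GDF15 at 69.8 and 66.0 against 20.6 FPKM and GADD45A at 43.3 and 43.6 against 15.3 FPKM. TGF-beta targets had medians of 0.25 and 0.38 (0.03 and 0.26 after that scaling), led by CTGF and back inside the random range with the most abundant transcript, and mesenchymal genes 0.24 and 0.18 (0.04 and 0.08 after it), with the matrix gene TNC at 5.48 and 5.32 against 2.23 FPKM. Stem cell regulators had medians of 0.17 in CD133+CD44+ (-0.0482 after it) and 0.29 in CD133-CD44- (0.17 after it), with the Polycomb gene BMI1 at 19.3 and 18.6 against 8.66 FPKM. Suprabasal squamous genes went both ways in CD133+CD44+ (median -0.14, within the random range), with SPRR1A, SPRR1B and SPRR2D at 1.40, 1.07 and 1.03 and the keratin genes KRT13, KRT4 and KRT10 at -1.27, -1.25 and 0.29. LCN2, a secreted iron-binding protein gene, was at 307 and 353 against 75.1 FPKM.

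The most abundant CD44 transcript, ENST00000415148, stood at 38.4, 35.4 and 26.1 FPKM in CD133+CD44+, CD133-CD44- and unsorted libraries, and ENST00000263398 at 32.5, 33.3 and 19.2 FPKM. Other list medians against unsorted cells, for CD133+CD44+ and CD133-CD44-, were -0.21 and -0.17 for cholesterol genes, -0.27 and -0.22 for NRF2 targets (SLC7A11 at 22.3 and 19.2 against 8.67 FPKM), 0.07 and 0.05 for ribosomal proteins, and -0.39 and -0.52 for 5 hedgehog genes, of which the last lay outside the random range although GLI2 was at 0.59 and 1.44.

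Immediate early genes were higher in both sorted libraries than in unsorted cells. Taking the labels as given, a difference between CD133+CD44+ and CD133-CD44- cells does not account for it as the whole cause. The median between the sorted libraries was -0.19 beside 1.45 and 1.81 against unsorted cells. Unsorted cells can also include cells with only 1 of the markers, which neither sorted library represents, so other differences by marker stay open. CD44 mRNA, however, was at 144 and 133 FPKM in CD133+CD44+ and CD133-CD44- against 84.5 FPKM unsorted. A bias by transcript length does not account for the immediate early genes either. Matched on expression and length, their list still lay at percentile 100 in both comparisons. A step that both sorted libraries shared, and unsorted cells did not, is a candidate explanation. The unsorted library was also the furthest in 75.7% of 329 varying genes outside the list. That share was nearly set by the 76.7% of 344 genes already seen, so it decides little. It also cannot tell a shared step from a peculiarity of the 1 unsorted library. Whether that step was the sort, the culture after it or the day of extraction was not tested, since each would separate the same libraries.

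In 37 of the 55 genes at least 2-fold apart between the sorted libraries, the most different transcript was listed at 0 in 1 sorted library. Whether 1 transcript's value accounts for these genes stays open: other transcripts had a median log2 ratio of 0.19, but only 12 of the 55 had any above 1 FPKM, and leaving out the most different transcript of genes chosen for their ratio lowers it by construction. Of the 40 genes with a known length, 50% differed most in a transcript under 500 nt, against 5% in matched random sets (central 95%, 0 to 12.5%). Short transcripts were thus over-represented among those 40 genes. Unstable values of short transcripts stay open as the cause, since the excess does not show that the values are unstable. Lengths were known for only 72.7% of genes. Reads shared with an overlapping gene on the same strand stay open as well: 33.3% of 39 annotated genes had such an overlap, against 17.9% in matched random sets (central 95%, 7.69 to 30.8%), but only 70.9% of genes were annotated. CD133 and CD44 status stays open too. Of the 55, 15 kept a 2-fold ratio when only transcripts above 0 in all 3 libraries were summed. That count cannot decide it, since 1 library per group does not separate marker status from other differences between the libraries.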
